A study of Oryza sativa with 8 samples.

How the data were processed

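Total RNA from rice cv. Kitaake (wild type) and from ospi1-2, a line in which OsPI1 is knocked down, was compared on 8 Agilent arrays of 2 colours. OsPI1 is named in the labels as a phosphate-limitation inducible gene. Plants stood in nutrient solution with 32 µM NaH2PO4 (1 ppm phosphorus) or without phosphorus (0 ppm), and roots and shoots were harvested on day 9. Each replicate pooled 3 plants. There were 2 biological replicates for each of 4 groups (shoot or root, without or with phosphorus). Each array carried both genotypes, so its 2 channels compare them directly. Replicate 1 had the knockdown in Cy5 and replicate 2 had it in Cy3 in every group, so dye orientation and replicate number are the same factor.

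Per the file headers, the scanner files were made with Agilent Feature Extraction 8.5.1.1 and give spot and local background intensity values for both channels without normalization. The same deposited files hold processed intensity values, from which Feature Extraction had subtracted background and removed dye trends within the array. They also hold a log10 ratio of processed Cy5 over Cy3, per the file headers. The deposited table of all arrays holds log10 ratios of knockdown over wild type. It equals the scanner log10 ratio, with the sign turned for replicate 2, to within 0.00499.

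Each array held 21495 probes that are not controls. Median spot intensity ranged from 538 to 898 in Cy5 and from 309 to 403 in Cy3. Median local background was 50 to 51 in Cy5 and 39 to 82 in Cy3, the 82 being replicate 1 of the roots with phosphorus. Between 91.8% and 97.7% of probes were well above background per channel. Arrays had 33 to 279 spots with an outlier mark of the scanner software, which were given no weight, and 2 to 56 saturated probes per channel. Arrays carry no counts, and their number limits the precision.

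Intensities were background-corrected with normexp (offset 50) and log2 ratios were normalized within each array by loess in limma 3.58.1 (R 4.3.3, statmod 1.5.0, and 1.17.8 of data.table). Probes had to be well above background in both replicates of at least 1 of 8 conditions, which 21058 probes (98.0%) met. For knockdown against wild type, lmFit and eBayes were run on the ratios of all 8 arrays (21026 probes), with 4 group means and a dye term, leaving 3 residual degrees of freedom. Contrasts were the 4 groups, their mean, the difference of the knockdown effect between phosphorus levels in each tissue, and its difference between root and shoot. For the phosphorus response of each genotype, the 16 channels were aligned between arrays (Aquantile) and fitted as separate channels (lmscFit, intraspot correlation 0.873). That fit took 20184 probes, and 874 probes with an outlier mark were left out of it. All limma tests were two-sided, with Benjamini-Hochberg adjustment over all probes of a comparison and a threshold of 0.05. Values are log2 changes ± SE of the fit, and n is 2 arrays per group.

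The comparisons, tests, filters, 16 testable gene lists and the rule for named genes were fixed before the data were examined. Lists were matched to the descriptions in the files, since 0 of the array identifiers were in the reference table. The descriptions name the nearest known sequence, often of another species. Gene identity here is that similarity, and no position on the genome is given. Lists were tested with camera at a preset correlation between genes of 0.01, on probes with a value on every array, adjusted over 192 tests of 16 lists. The same tests were run with an estimated correlation and with fry, a rotation test. None of the 57 calls held with an estimated correlation (0 calls, smallest adjusted p = 0.357). Of the 57, 35 were also called by fry, which called 51 in all. The fixed lists were phosphate sensing and transport, phosphate scavenging, membrane lipid remodelling, glycolytic bypass, photosynthesis, iron, nitrogen, sucrose and starch, defence proteins, jasmonate, phenylpropanoids, heat shock proteins, cytosolic ribosomal proteins, cell wall, histones and cell cycle, and root markers. The photosynthesis and root marker lists also serve as markers of the other tissue.

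A fixed list for OsPI1 and its relatives matched 0 probes by description, so the level of the targeted transcript could not be read here. A probe for it may be among the 5565 described as unknown. A list of phosphate transporters and SPX proteins, and a jasmonate list without potassium channels, were added after the descriptions were read and before any ratio was seen. Lists of diterpenoid enzymes, the tryptophan branch and transposable elements were chosen after the ratios were seen.

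Named genes are, per comparison, the 12 largest positive and 12 largest negative changes among probes past the threshold. They need a gene symbol or an informative description and the same direction in both replicates. Up to 4 members past the threshold were added per fixed list. The wording that counts as informative (8669 probes) was set, and once corrected, after ratios had been seen, while 5565 probes are described as unknown. A probe that was not well above background in both replicates of a condition is given as a lower bound of its fold.

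The fits were tested on simulated data with known changes. In the 4 groups, 94% to 98% of changes of 0.5 on the log2 scale were recovered, against 14% to 26% of changes of 0.25. False calls made up 4.37% to 10% of calls on ratios. For the phosphorus responses, 66% to 78% of changes of 1 were recovered and 1.10% to 5.15% of calls were false. In simulated lists of independent probes, 16 of 16 moved lists were called with the preset correlation, 11 with an estimated one, and 2 calls fell on other lists. These simulated probes had no correlation between genes, so they cannot show which correlation setting suits the real lists.

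Alternatives were the deposited processed signals, no background correction, no signal filter, a stricter filter (19455 probes), median centring in place of loess, and no dye term. Further ones were arrays of the same tissue only, a minimum change of 1, the deposited table of ratios, other alignments between arrays, channels of one genotype only, and leaving out each array in turn. A group left with 1 array was assumed to vary like the other groups, and the intraspot correlation of all arrays was kept. A fit of tissue means without phosphorus groups was added after the results were seen, and both list changes after the descriptions were read. A block for slide or scan day was not run, since each array was its own slide and all were scanned on the same day. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.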

Results

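Transcript levels in rice shoots and roots were measured on 8 Agilent arrays of 2 colours, each comparing ospi1-2, an OsPI1 knockdown line, with wild type. The arrays form 4 groups with 2 biological replicates each: shoots without phosphorus, shoots with phosphorus, roots without phosphorus and roots with phosphorus. OsPI1 is a gene that phosphate limitation induces, and the series asks how transcripts change during phosphorus deficiency in plants labelled as its knockdown. No probe description named OsPI1 or its relatives (0 probes), so no probe for OsPI1 could be identified and its level could not be read here. Median intensities were 538 to 898 in Cy5 and 309 to 403 in Cy3, against local backgrounds of 39 to 82. In Cy5 they were 538 to 644 on arrays without phosphorus and 719 to 898 on arrays with it. Plants without and with phosphorus were never on the same array. Each phosphorus response therefore compares arrays that also differed in Cy5 signal. Across probes, which are not independent replicates, the log2 ratios of the 2 replicates correlated with r = 0.334 and r = 0.316 in shoots without and with phosphorus. The values in roots were r = 0.0873 and r = 0.156. Deviations of the replicates from their group mean also correlated between groups (r = 0.345 to 0.528 across probes in 6 pairs of groups), and the dye term of the fit carries this shared part. The array with the highest Cy3 background was replicate 1 of roots with phosphorus.

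The first question was how wild type shoots responded to 9 days without phosphorus. The phosphate transporters OsPT1 and Pht1-2, purple acid phosphatases and a galactolipid synthase rose, while a plastid chaperonin and a plastid ribosomal protein fell. AK107245, similar to ids4, a protein with the SPX domain that senses phosphate status, rose 17.6-fold (log2 4.13 ± 0.17, adjusted p = 1.29e-07, n = 2 arrays per phosphorus level). A monogalactosyldiacylglycerol synthase, AK064148, which makes galactolipids that replace phospholipids, rose 15.0-fold (log2 3.91 ± 0.18, adjusted p = 4.35e-07). Of 20184 probes, 1597 passed the threshold, 758 higher and 839 lower without phosphorus, and 477 of them changed by at least 1 on the log2 scale. The phosphate transporters OsPT1 (AK063990, log2 3.04 ± 0.35, adjusted p = 0.000511) and Pht1-2 (AK101380, log2 2.71 ± 0.23, adjusted p = 4.21e-05) rose, as did a second ids4-like probe (AK063544, log2 2.34 ± 0.19). Lipoxygenase L-2 (AK073529, log2 3.20 ± 0.40), a bnuc2-like nuclease (AK106059, log2 2.59 ± 0.21) and an aminotransferase-like protein (AK100259, log2 2.42 ± 0.31) were also among the largest increases. An RD22-like dehydration-responsive gene (AK105947, log2 -2.39 ± 0.60, adjusted p = 0.0312) and aspartate kinase-homoserine dehydrogenase (AK068391, log2 -2.29 ± 0.36, adjusted p = 0.00277) showed the largest decreases among the named genes, followed by a subtilase (AK066488, log2 -2.13 ± 0.28). Other large decreases were chloroplast ribosomal RNA (AK059621, log2 -2.06 ± 0.48), the chaperonin Cpn21 (AK073762, log2 -1.76 ± 0.23) and plastid ribosomal protein CL24 (AK060024, log2 -1.75 ± 0.32). Dropping replicate 1 of shoots without phosphorus gave 534 probes. Leaving out replicate 1 or 2 of shoots with phosphorus gave 372 (72.0% higher, against 47.5%) and 569 probes.

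Among the fixed lists in wild type shoots, phosphate scavenging genes, mostly acid phosphatases, stood above other genes. Here 5 of 22 rose and 0 fell (6 and 0 adjusted over the list alone) (median log2 0.14, adjusted p = 0.00217, 0.408 with an estimated correlation and 0.0088 by fry). Purple acid phosphatases led this list, with AK071643 at log2 2.62 ± 0.15, AK070684 at log2 2.15 ± 0.28 and PAP22 (AK073222) at log2 1.52 ± 0.23. In phosphate sensing and transport 2 of 7 rose and 0 fell (3 and 0 adjusted over the list alone) (median log2 0.45, adjusted p = 0.0167, 0.416 with an estimated correlation and 0.0133 by fry). In the list of transporters and SPX proteins drawn from the descriptions, 5 of 11 rose and 0 fell (6 and 0 adjusted over the list alone) (median log2 0.57, adjusted p = 2.95e-07, 0.0773 with an estimated correlation and 0.000922 by fry). In the glycolytic bypass list, enzymes that spare phosphate or ATP, 2 of 14 rose and 1 fell (3 and 1 adjusted over the list alone) (median log2 0.27, adjusted p = 0.0469, 0.515 with an estimated correlation and 0.0964 by fry). Its member phosphoenolpyruvate carboxylase kinase (AK066885) was at log2 1.25 ± 0.19. Phenylpropanoid genes were shifted upward. Here 11 of 89 rose and 3 fell (13 and 3 adjusted over the list alone) (median log2 0.18, adjusted p = 0.000179, 0.357 with an estimated correlation and 0.00806 by fry). A cinnamoyl-CoA reductase of lignin synthesis (AK064401) was at least 4.32-fold higher, and chalcone synthase (AK061132) rose by log2 1.35 ± 0.30. In the jasmonate list 4 of 34 rose and 0 fell (4 and 0 adjusted over the list alone) (median log2 0.081, adjusted p = 0.0367, 0.416 with an estimated correlation and 0.0286 by fry), and without the potassium channels that its pattern matched by letters, the median gave adjusted p = 0.0233, 0.144 with an estimated correlation and 0.0114 by fry. Cytosolic ribosomal proteins were shifted downward. Here 9 of 31 fell and 0 rose (21 and 1 adjusted over the list alone) (median log2 -0.59, adjusted p = 1.2e-09, 0.357 with an estimated correlation and 0.00383 by fry). Its L1 protein (AK060711) was at log2 -1.002 ± 0.21. Photosynthesis genes were lower as a list. Here 5 of 35 fell and 1 rose (6 and 2 adjusted over the list alone) (median log2 -0.20, adjusted p = 0.0131, 0.515 with an estimated correlation and 0.133 by fry), although a Rubisco small subunit (AK059909) rose by log2 0.92 ± 0.19.

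Camera called no shift of the other lists in wild type shoots, although members changed, while fry called membrane lipid remodelling and root markers (adjusted p = 0.0286 and 0.0477). In membrane lipid remodelling 3 of 19 rose and 0 fell (3 and 0 adjusted over the list alone) (adjusted p = 0.186), among them DGD2 (AK067931, log2 1.21 ± 0.19). In sucrose and starch 6 of 62 rose and 2 fell (6 and 2 adjusted over the list alone) (adjusted p = 0.387), including sucrose-phosphatase (AK071525, log2 2.42 ± 0.17), granule-bound starch synthase II (AK102058, log2 2.19 ± 0.27) and a cell wall invertase (AK072276, log2 -1.64 ± 0.17). In nitrogen uptake and assimilation 4 of 37 rose and 1 fell (7 and 2 adjusted over the list alone) (adjusted p = 0.147), including nitrate reductase (AK102178, log2 1.28 ± 0.31). Defence proteins moved both ways. Here 3 of 69 rose and 3 fell (5 and 3 adjusted over the list alone) (adjusted p = 0.242). Its member chitinase (AK070067) was at log2 -1.80 ± 0.18. For heat shock proteins 4 of 57 rose and 6 fell (5 and 7 adjusted over the list alone) (adjusted p = 0.891). Its member HSP101 (AK105433) was at log2 1.17 ± 0.13. In the cell wall list 3 of 60 rose and 1 fell (4 and 2 adjusted over the list alone) (adjusted p = 0.0892), and in the iron list 0 of 13 rose and 1 fell (2 and 1 adjusted over the list alone) (adjusted p = 0.644). For histones and cell cycle genes 1 of 17 fell and 0 rose (1 and 0 adjusted over the list alone) (adjusted p = 0.242), and for root markers 1 of 8 fell and 0 rose (1 and 0 adjusted over the list alone) (adjusted p = 0.242).

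In wild type roots, purple acid phosphatases, a phosphate transporter, a galactolipid synthase and chalcone synthase rose without phosphorus, while a light-harvesting protein, a nicotianamine synthase and an ammonium transporter fell. The purple acid phosphatase PAP22 (AK073222), which releases phosphate from organic compounds, rose 35.0-fold (log2 5.13 ± 0.23, adjusted p = 9.8e-08, n = 2 arrays per phosphorus level). Chalcone synthase (AK061132), the entry enzyme of flavonoid synthesis, rose 31.2-fold (log2 4.97 ± 0.30, adjusted p = 9.62e-07), and the galactolipid synthase AK064148 rose 19.7-fold (log2 4.30 ± 0.18, adjusted p = 6.98e-08). A light-harvesting chlorophyll a/b-binding protein (AK061619) fell (log2 -4.47 ± 0.46, adjusted p = 9.17e-05). In all, 1463 of 20184 probes passed, 861 higher and 602 lower, with 604 changed by at least 1. Other large increases were purple acid phosphatases AK110804 (log2 4.24 ± 0.24) and AK066273 (log2 3.14 ± 0.22), ids4-like AK107245 (log2 3.75 ± 0.17), a lectin (AK103206, log2 3.54 ± 0.51) and a metallophosphatase (AK106533, log2 3.33 ± 0.20). Large decreases outside photosynthesis included nicotianamine synthase 2 (AK112011, adjusted p = 0.00211), which makes an iron chelator and was saturated with phosphorus in 1 of 2 replicates, and an aminotransferase (AK064774, log2 -2.67 ± 0.34). Without replicate 1 of roots lacking phosphorus 689 probes passed, and without replicate 1 or 2 of roots with phosphorus 1391 and 779 passed.

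Of the phosphate scavenging list in wild type roots, 9 of 22 rose and 1 fell (9 and 2 adjusted over the list alone) (median log2 0.15, adjusted p = 1.82e-05, 0.367 with an estimated correlation and 0.00383 by fry). For phosphate sensing and transport 3 of 7 rose and 0 fell (3 and 1 adjusted over the list alone) (median log2 0.20, adjusted p = 0.0233, 0.416 with an estimated correlation and 0.0088 by fry), led by high-affinity transporter 2 (AK108907, log2 2.53 ± 0.22, adjusted p = 2.38e-05). The list of transporters and SPX proteins drawn from the descriptions was higher. Here 7 of 11 rose and 0 fell (7 and 1 adjusted over the list alone) (median log2 2.11, adjusted p = 3.24e-08, 0.0773 with an estimated correlation and 0.000711 by fry). Glycolytic bypass genes were higher as a list. Here 3 of 14 rose and 0 fell (5 and 1 adjusted over the list alone) (median log2 0.27, adjusted p = 0.00668, 0.439 with an estimated correlation and 0.044 by fry). Its member phosphoenolpyruvate carboxylase (AK070742) was at log2 1.48 ± 0.16 and the alternative oxidase AOX1a (AK064040) at log2 1.23 ± 0.27. Photosynthesis genes, which here also mark shoot tissue, were lower. Here 13 of 35 fell and 0 rose (14 and 0 adjusted over the list alone) (median log2 -0.37, adjusted p = 7.14e-11, 0.408 with an estimated correlation and 0.0129 by fry), among them CP24 (AK066070) at log2 -3.45 ± 0.32. Root markers went the other way, with 7 of 8 positive and 0 called (median log2 0.28, adjusted p = 0.0443, 0.416 with an estimated correlation and 0.0171 by fry). Beside these tissue markers, cell wall genes were higher. Here 9 of 60 rose and 1 fell (10 and 1 adjusted over the list alone) (median log2 0.10, adjusted p = 0.00842, 0.501 with an estimated correlation and 0.0777 by fry). Its member beta-expansin EXPB3 (AK100959) was at log2 2.46 ± 0.18 and EXPB2 (AK061068) at log2 1.24 ± 0.25. In the iron list 5 of 13 fell and 0 rose (5 and 1 adjusted over the list alone) (median log2 -0.36, adjusted p = 0.0446, 0.416 with an estimated correlation and 0.039 by fry), including the phytosiderophore transporter YS1 (AK070304, log2 -1.39 ± 0.12). Defence proteins were lower as a list. Here 5 of 69 fell and 2 rose (9 and 3 adjusted over the list alone) (median log2 -0.12, adjusted p = 0.0159, 0.408 with an estimated correlation and 0.0327 by fry). Its member class III chitinase OsChib3a (AK100973) was at log2 -2.42 ± 0.25.

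Camera did not call the remaining lists in wild type roots. By fry, membrane lipid remodelling (adjusted p = 0.0088), phenylpropanoids (0.0159), heat shock proteins (0.0298) and cytosolic ribosomal proteins (0.0478) were called. In membrane lipid remodelling 4 of 19 rose and 0 fell (4 and 0 adjusted over the list alone) (adjusted p = 0.0952), including glycerophosphodiester phosphodiesterase (AK071836, log2 3.13 ± 0.13). Phenylpropanoid members moved in both directions. Here 15 of 89 rose and 7 fell (18 and 9 adjusted over the list alone) (adjusted p = 0.141). Its member phenylalanine ammonia-lyase (AK067801) was at log2 -1.74 ± 0.34. In the nitrogen list 4 of 37 fell and 3 rose (5 and 3 adjusted over the list alone) (adjusted p = 0.559). Its member ammonium transporter OsAMT1 (AK107204) was at log2 -2.35 ± 0.19. For sucrose and starch 9 of 62 fell and 4 rose (12 and 7 adjusted over the list alone) (adjusted p = 0.199), for jasmonate 2 of 34 rose and 1 fell (4 and 1 adjusted over the list alone) (adjusted p = 0.75), and for heat shock proteins 5 of 57 rose and 1 fell (5 and 1 adjusted over the list alone) (adjusted p = 0.221). Cytosolic ribosomal proteins had no called member (0 of 31 by limma, 0 higher and 0 lower adjusted over the list alone, list adjusted p = 0.0725). In the histone list 0 of 17 rose and 0 fell (0 and 0 adjusted over the list alone) (adjusted p = 1.0).

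**Figure D1:**
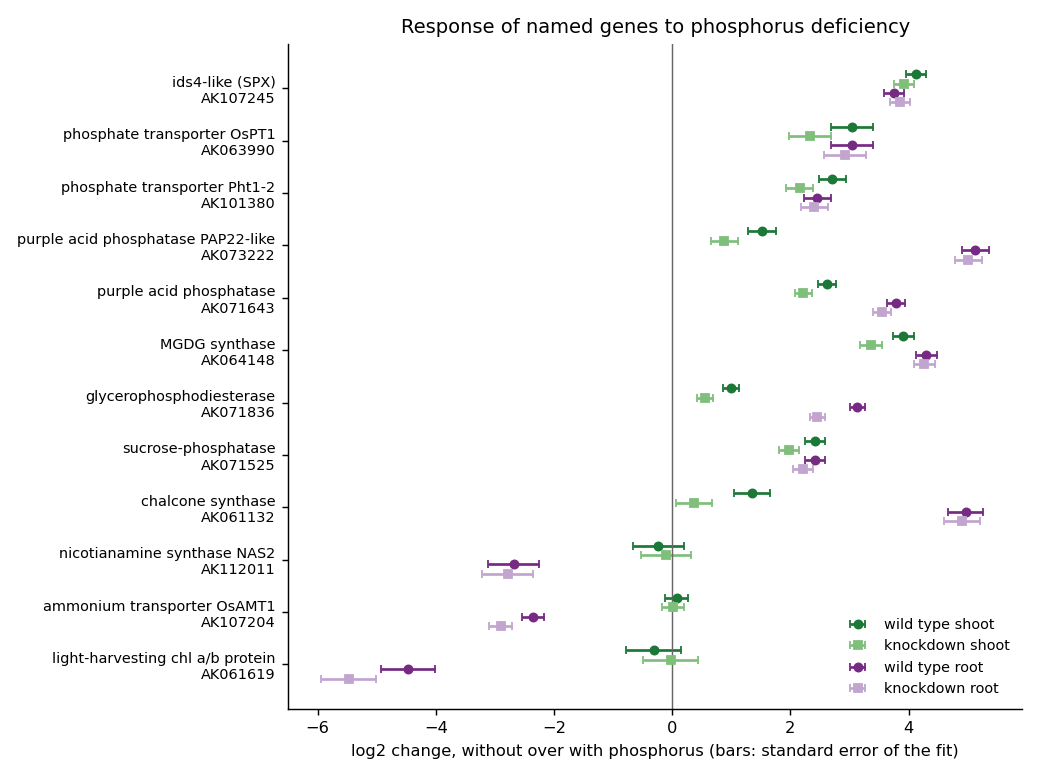
Fitted log2 change without against with phosphorus for 12 genes, with SE bars of the fit, in wild type shoot, knockdown shoot, wild type root and knockdown root (2 arrays per phosphorus level, shared by genotypes). Phosphate genes such as AK107245 lie above 0 in all 4 responses, at log2 4.13, 3.92, 3.75 and 3.86.

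In knockdown shoots the same question was asked of the line labelled as an OsPI1 knockdown. The phosphate transporters OsPT1 and Pht1-2, the galactolipid synthase and a starch synthase rose without phosphorus, and a chitinase, an isoflavone reductase homolog and flavanone 3-hydroxylase fell. The ids4-like gene AK107245 rose 15.1-fold (log2 3.92 ± 0.17, adjusted p = 2.39e-07, n = 2 arrays per level) and the galactolipid synthase AK064148 rose 10.3-fold (log2 3.36 ± 0.18, adjusted p = 1.97e-06). A chitinase (AK070067, log2 -1.87 ± 0.18, adjusted p = 0.000332), an isoflavone reductase homolog (AK110682, log2 -1.73 ± 0.40, adjusted p = 0.0471) and flavanone 3-hydroxylase (AK071218, log2 -1.30 ± 0.14, adjusted p = 0.000547) fell. Of all probes 481 passed, 219 higher and 262 lower, 189 of them by at least 1. OsPT1 (AK063990, log2 2.33 ± 0.35), Pht1-2 (AK101380, log2 2.16 ± 0.23) and granule-bound starch synthase II (AK102058, log2 1.93 ± 0.27) were among the strongest increases, and a thaumatin-like protein (AK102970, log2 -1.44 ± 0.21) among the decreases. In phosphate scavenging 3 of 22 rose and 0 fell (4 and 1 adjusted over the list alone) (median log2 0.10, adjusted p = 0.00371, 0.416 with an estimated correlation and 0.0286 by fry), and in phosphate sensing and transport 2 of 7 rose and 0 fell (2 and 0 adjusted over the list alone) (median log2 0.31, adjusted p = 0.0385, 0.416 with an estimated correlation and 0.023 by fry). Glycolytic bypass (1 up and 0 down of 14, 1 and 0 adjusted over the list alone, median log2 0.26, adjusted p = 0.0114, 0.535 with an estimated correlation and 0.145 by fry), jasmonate (1 up and 0 down of 34, 1 and 0 adjusted over the list alone, median log2 0.10, adjusted p = 0.0103, 0.408 with an estimated correlation and 0.044 by fry) and phenylpropanoid lists (3 up and 2 down of 89, 3 and 2 adjusted over the list alone, median log2 0.073, adjusted p = 0.0131, 0.408 with an estimated correlation and 0.0298 by fry) were shifted upward. Photosynthesis (1 up and 4 down of 35, 1 and 5 adjusted over the list alone, median log2 -0.15, adjusted p = 0.0167, 0.408 with an estimated correlation and 0.0791 by fry) and cytosolic ribosomal protein lists (0 up and 0 down of 31, 0 and 0 adjusted over the list alone, median log2 -0.14, adjusted p = 0.0127, 0.64 with an estimated correlation and 0.245 by fry) were lower by camera alone. Fry alone called sucrose and starch and root markers (adjusted p = 0.00383 and 0.044, camera 0.185 and 0.0961). With the processed signals 170 probes passed (65.9% higher, against 45.5%), while without the dye term 729 and with the knockdown channels alone 726 passed. Dropping replicate 1 of shoots without phosphorus gave 225 probes, and leaving out replicate 1 or 2 of shoots with phosphorus gave 77 (76.6% higher) and 140 (60.7% higher).

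Knockdown roots without phosphorus raised the acid phosphatase PAP22, chalcone synthase and a pair of expansins, and lowered a light-harvesting protein, a nicotianamine synthase and the ammonium transporter OsAMT1. PAP22 (AK073222) rose 32.3-fold (log2 5.01 ± 0.23, adjusted p = 1.49e-07, n = 2 arrays per level) and chalcone synthase AK061132 rose 29.9-fold (log2 4.90 ± 0.30, adjusted p = 1.31e-06). The light-harvesting protein AK061619 fell most among the named genes (log2 -5.47 ± 0.46, adjusted p = 1.85e-05), and the ammonium transporter OsAMT1 (AK107204) fell too (log2 -2.90 ± 0.19, adjusted p = 2.41e-06). In total 2021 probes passed, 1178 higher and 843 lower, 718 of them by at least 1. In phosphate scavenging 8 of 22 rose and 1 fell (9 and 2 adjusted over the list alone) (median log2 0.19, adjusted p = 0.000538, 0.408 with an estimated correlation and 0.00383 by fry), and in the glycolytic bypass 4 of 14 rose and 1 fell (6 and 1 adjusted over the list alone) (median log2 0.29, adjusted p = 0.0167, 0.566 with an estimated correlation and 0.0791 by fry). In photosynthesis 14 of 35 fell and 0 rose (17 and 1 adjusted over the list alone) (median log2 -0.48, adjusted p = 7.14e-11, 0.357 with an estimated correlation and 0.00383 by fry), while of the root markers 2 of 8 rose and 0 fell (2 and 0 adjusted over the list alone) (median log2 0.41, adjusted p = 0.000666, 0.408 with an estimated correlation and 0.0106 by fry), led by the root-specific RCc3 (AK062381, log2 1.20 ± 0.20). Beside these tissue markers, cell wall genes were higher. Here 17 of 60 rose and 1 fell (19 and 2 adjusted over the list alone) (median log2 0.19, adjusted p = 0.000429, 0.458 with an estimated correlation and 0.0327 by fry). Its member EXPB3 (AK100959) was at log2 2.66 ± 0.18 and the expansin Os-EXP-1 (AK069548) at log2 1.32 ± 0.24. In the iron list 5 of 13 fell and 1 rose (5 and 1 adjusted over the list alone) (median log2 -0.39, adjusted p = 0.0245, 0.597 with an estimated correlation and 0.0462 by fry). Its member nicotianamine synthase 2 (AK112011, adjusted p = 0.00148), saturated with phosphorus in 1 of 2 replicates, fell. Phosphate sensing and transport was not called by camera but was by fry (adjusted p = 0.0892 and 0.0088), and 3 of 7 rose and 0 fell (3 and 1 adjusted over the list alone). The same held for membrane lipid remodelling (0.258 and 0.0111), phenylpropanoids (0.186 and 0.0159, 17 up and 8 down of 89) and defence proteins (0.125 and 0.0376). In the list of transporters and SPX proteins 7 of 11 rose and 0 fell (7 and 1 adjusted over the list alone) (median log2 1.86, adjusted p = 2.23e-06, 0.0773 with an estimated correlation and 0.000711 by fry). Leaving out replicate 1 or 2 of roots without phosphorus gave 1062 and 1163 probes. Without replicate 1 or 2 of roots with phosphorus 2123 and 947 passed.

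The direct comparison of the knockdown with wild type asked which transcripts differed between the ospi1-2 line and wild type. No other knockdown line was compared, so dependence of these transcripts on OsPI1 itself was not tested. In shoots without phosphorus, knockdown plants had more transcript of a laccase and of tryptophan decarboxylase, and less of the acid phosphatase PAP22, a galactolipid synthase and a nuclease. The laccase LAC2-1 homolog (AK103094), of a family that polymerizes lignin, was 4.16-fold higher (log2 2.06 ± 0.072, adjusted p = 0.00022, n = 2 arrays). Tryptophan decarboxylase (AK069031), which makes tryptamine, was 3.86-fold higher (log2 1.95 ± 0.090, adjusted p = 0.000617). A galactolipid synthase (AK064148, log2 -0.64 ± 0.070, adjusted p = 0.0118), PAP22 (AK073222, log2 -0.64 ± 0.10, adjusted p = 0.0297) and nuclease I (AK059608, log2 -0.76 ± 0.067, adjusted p = 0.00716) were lower. Of 21026 probes 890 passed, 481 higher and 409 lower (54.0% higher), and 56 of them differed by at least 1. Further large increases were an LTR-retrotransposon-like probe (AK106705, log2 1.76 ± 0.084), glutathione S-transferase OsGSTU12 (AK063773, log2 1.69 ± 0.16), NADP-dependent malic enzyme (AK070360, log2 1.62 ± 0.22), a hydroxycinnamoyl/benzoyltransferase (AK061327, log2 1.55 ± 0.085) and lipoxygenase CM-LOX2 (AK066825, log2 1.49 ± 0.19). Among the named genes, the largest decreases were a putative hydrogenase protein (AK060417, log2 -1.42 ± 0.11, adjusted p = 0.00579), an early light-inducible protein (AK062972, log2 -0.99 ± 0.14) and a SUVH2-like gene (AK067172, log2 -0.94 ± 0.065, adjusted p = 0.00328), whose relatives are histone methyltransferase-like proteins. A cyclophilin (AK058898, log2 -0.92 ± 0.14), the potassium transporter HAK4 (AK068820, log2 -0.83 ± 0.14) and flavonoid 3-hydroxylase (AK064736, log2 -0.81 ± 0.10) were lower too. With no dye term 136 probes passed, and AK064148, PAP22 and CM-LOX2 no longer did, while median centring alone gave 19 (73.7% higher). Dropping replicate 1 or 2 of this group gave 165 (61.8% higher) and 170 (66.5% higher).

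Of the phosphate scavenging list in knockdown shoots without phosphorus, 5 of 25 were lower and 0 higher (9 and 0 adjusted over the list alone) (median log2 -0.10, adjusted p = 0.00057, 0.408 with an estimated correlation and 0.0106 by fry). Phosphate sensing and transport was also lower as a list, with 1 of 7 positive and none called (0 by limma; median log2 -0.14, adjusted p = 0.0429, 0.445 with an estimated correlation and 0.117 by fry). In the list of transporters and SPX proteins drawn from the descriptions 2 of 11 were lower and 0 higher (5 and 0 adjusted over the list alone) (median log2 -0.18, adjusted p = 0.000151, 0.1 with an estimated correlation and 0.00357 by fry). Membrane lipid remodelling was called by neither camera nor fry (adjusted p = 0.0931 and 0.117), although 3 of 19 were lower and 0 higher (3 and 1 adjusted over the list alone), including DGD2 (AK067931, log2 -0.37 ± 0.061) and glycerophosphodiester phosphodiesterase (AK071836, log2 -0.29 ± 0.044). Of cytosolic ribosomal proteins 6 of 31 were higher and 0 lower (19 and 1 adjusted over the list alone) (median log2 0.29, adjusted p = 6.66e-07, 0.515 with an estimated correlation and 0.101 by fry). L1 (AK060711) was at log2 0.47 ± 0.087. Histone and cell cycle genes were higher as a list. Here 1 of 17 were higher and 0 lower (3 and 0 adjusted over the list alone) (median log2 0.11, adjusted p = 0.0285, 0.501 with an estimated correlation and 0.101 by fry). Its member histone H4 (AK105816) was at log2 0.39 ± 0.068. In the cell wall list 1 of 63 were lower and 0 higher (5 and 1 adjusted over the list alone) (median log2 -0.044, adjusted p = 0.0426, 0.416 with an estimated correlation and 0.0428 by fry). Defence proteins were called by neither (adjusted p = 0.52 and 0.0774), although 8 of 71 were higher and 2 lower (13 and 7 adjusted over the list alone), including PR-1a (AK071103, log2 1.09 ± 0.14) and class III chitinase OsChib3a (AK100973, log2 1.09 ± 0.10). Phenylpropanoid members went both ways. Here 7 of 90 were higher and 6 lower (12 and 9 adjusted over the list alone) (adjusted p = 0.678). Nitrate reductase (AK102178, log2 0.81 ± 0.12) and alternative oxidase AOX1b (AK107376, log2 0.64 ± 0.082) were higher, and sucrose-phosphatase (AK071525, log2 -0.48 ± 0.068) and HSP70 (AK071518, log2 -0.46 ± 0.040) were lower.

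**Figure D2:**
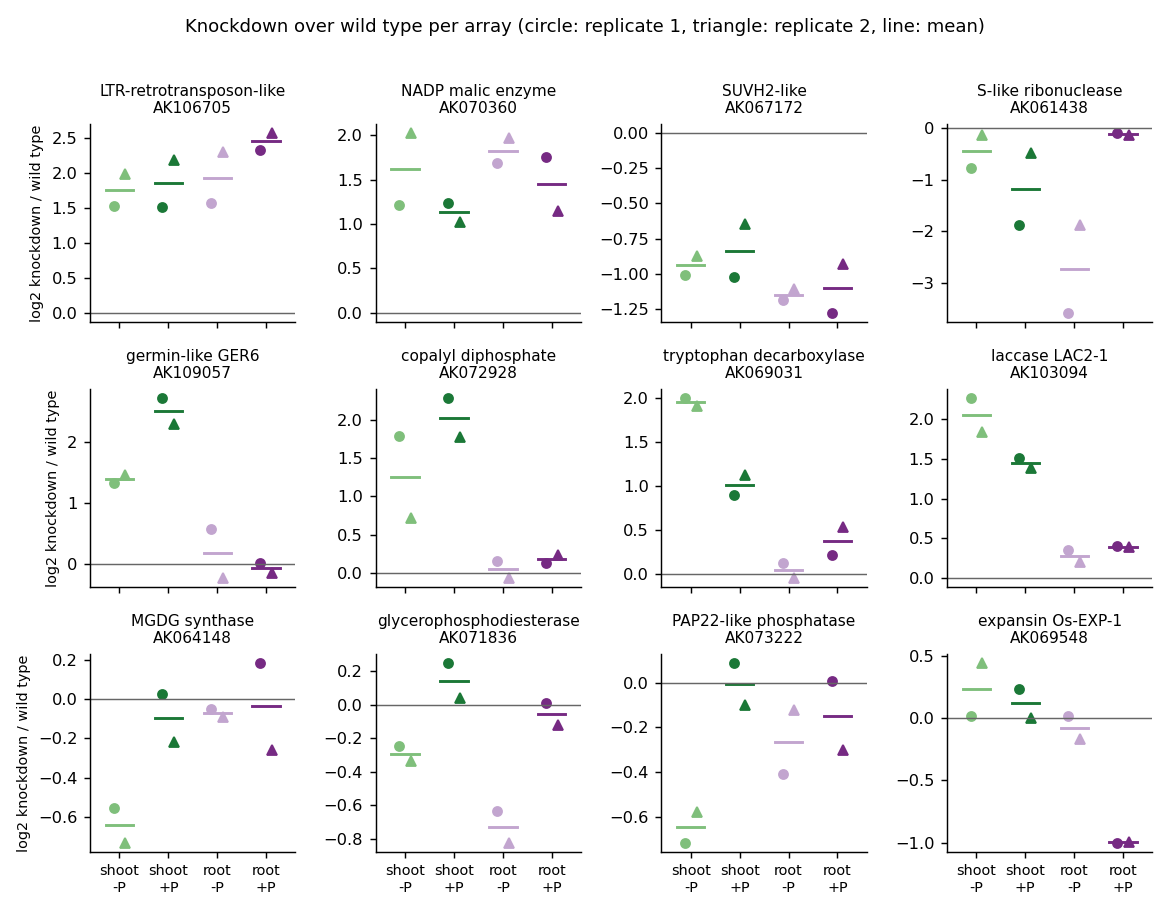
The log2 ratio of knockdown over wild type on each array for 12 genes in the 4 groups, with circles for replicate 1, triangles for replicate 2, a line at their mean and a separate vertical scale per panel. AK106705 lies above 0 and AK067172 below 0 in all groups, with group means of log2 1.76 to 2.45 and -1.15 to -0.84.

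In shoots with phosphorus, the knockdown had more transcript of a germin-like protein, flavanone 3-hydroxylase and a diterpene cyclase, and 350 of 375 called changes were increases. Germin-like protein 6 (AK109057), of a family with roles in defence, was 5.66-fold higher (log2 2.50 ± 0.14, adjusted p = 0.00122, n = 2 arrays). A copalyl diphosphate synthase-like gene (AK072928, log2 2.03 ± 0.18, adjusted p = 0.00489), the diterpene cyclase OsDTC1 (AK068310, log2 1.87 ± 0.23, adjusted p = 0.0182) and deoxyxylulose phosphate synthase (AK100909, log2 1.71 ± 0.12, adjusted p = 0.00324), enzymes on the path to diterpenes, were higher. Cytochromes P450 of the PM-II type (AK105913, log2 2.34 ± 0.34, and AK059010, log2 1.53 ± 0.047) and of the wheat N-1 type (AK070167, log2 2.19 ± 0.16) and an isoflavone reductase homolog (AK110682, log2 2.27 ± 0.17) rose with them. The other 25 called probes were lower (93.3% higher in all), and 59 probes differed by at least 1. Lower were the putative hydrogenase protein AK060417 (log2 -1.53 ± 0.11, adjusted p = 0.00371), SUVH2-like AK067172 (log2 -0.84 ± 0.065, adjusted p = 0.00377), beta-amyrin synthase (AK072702, log2 -0.58 ± 0.056) and cycloartenol synthase (AK066327, log2 -0.50 ± 0.048), which make triterpenes and sterols. Defence proteins were higher as a list. Here 8 of 71 were higher and 0 lower (16 and 1 adjusted over the list alone) (median log2 0.046, adjusted p = 0.00105, 0.408 with an estimated correlation and 0.0159 by fry), among them probenazole-inducible PBZ1 (AK099157, log2 1.53 ± 0.18, adjusted p = 0.0138) and an endochitinase (AK061042, log2 0.91 ± 0.094). Phenylpropanoid genes were higher. Here 9 of 90 were higher and 0 lower (16 and 0 adjusted over the list alone) (median log2 0.034, adjusted p = 0.00129, 0.408 with an estimated correlation and 0.0229 by fry). Its member flavanone 3-hydroxylase (AK071218) was at log2 1.32 ± 0.052, adjusted p = 0.000429 and chalcone synthase (AK061132) at log2 0.79 ± 0.12. Cytosolic ribosomal proteins had 3 of 31 positive and 0 called by limma (median log2 -0.12, adjusted p = 1.82e-05, 0.551 with an estimated correlation and 0.295 by fry). Without the dye term 138 probes passed, and AK105913, OsDTC1 and PBZ1 no longer did. Leaving out replicate 1 or 2 of this group gave 21 and 57.

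Knockdown roots without phosphorus had less transcript of an S-like ribonuclease, alanine aminotransferase and a purple acid phosphatase, and more of malic enzyme and of a pair of transposon-like probes. The drought-induced S-like ribonuclease (AK061438), which degrades RNA, changed by log2 -2.72 ± 0.27, adjusted p = 0.0357 (n = 2 arrays), alanine aminotransferase (AK107237) by log2 -1.36 ± 0.070, adjusted p = 0.00256, and glycerophosphodiester phosphodiesterase (AK071836) by log2 -0.73 ± 0.044, adjusted p = 0.0034. Malic enzyme (AK070360) was 3.54-fold higher (log2 1.82 ± 0.22, adjusted p = 0.0459), and a reverse transcriptase-like probe (AK064186) was at least 2.13-fold higher (adjusted p = 0.00256). Of 57 probes called, 42 were higher and 15 lower (73.7% higher), 14 of them by at least 1. Also higher were LTR-retrotransposon-like AK106705 (log2 1.93 ± 0.084, adjusted p = 0.00129), a multidrug resistance protein homolog (AK106698, log2 1.13 ± 0.090), amygdalin hydrolase-like AK070962 (log2 1.01 ± 0.092) and a syntaxin (AK065950, log2 0.89 ± 0.10). Also lower were SUVH2-like AK067172 (log2 -1.15 ± 0.065, adjusted p = 0.00313), peroxidases AK099751 and AK073767 (log2 -0.72 ± 0.054 and -0.66 ± 0.076), a purple acid phosphatase (AK066273, log2 -0.68 ± 0.076) and the potassium transporter HAK1 (AK100669, log2 -0.50 ± 0.050). In phosphate scavenging 2 of 25 were lower and 0 higher (2 and 0 adjusted over the list alone) (median log2 -0.10, adjusted p = 6.94e-08, 0.357 with an estimated correlation and 0.0088 by fry). In the list of transporters and SPX proteins drawn from the descriptions, none of 11 was called (0 by limma), with median log2 -0.12, adjusted p = 0.00028, 0.1 with an estimated correlation and 0.0173 by fry. Phenylpropanoids were called by neither camera nor fry (adjusted p = 0.891 and 0.423), with 2 members higher, flavanone 3-hydroxylase-like AK068438 (log2 0.57 ± 0.065) and a cinnamoyl-CoA reductase (AK062411, log2 0.52 ± 0.040). With no dye term 12 probes passed (83.3% higher), and AK106705, AK070360, AK061438 and AK071836 no longer did, while root arrays alone gave 4 (100% higher). Dropping replicate 1 or 2 of this group gave 22 and 10.

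In roots with phosphorus, knockdown plants had less transcript of an expansin, 3 peroxidases and delta-cadinene synthase and more of malic enzyme and a nicotianamine synthase. Delta-cadinene synthase (AK071447, log2 -1.28 ± 0.14, adjusted p = 0.0184, n = 2 arrays), a sesquiterpene enzyme, and arginine decarboxylase (AK058573, log2 -1.21 ± 0.12, adjusted p = 0.014), which makes polyamine precursors, were lower. So were the expansin Os-EXP-1 (AK069548, log2 -0.998 ± 0.11, adjusted p = 0.0172), a lipid transfer protein (AK060340, log2 -0.94 ± 0.068), a plasma membrane aquaporin-like protein (AK058613, log2 -0.82 ± 0.079) and 3 peroxidases (AK104633, AK066855 and AK073833, log2 -0.93, -0.86 and -0.83). Higher were LTR-retrotransposon-like AK106705 (log2 2.45 ± 0.084, adjusted p = 0.000387), malic enzyme AK070360 (log2 1.45 ± 0.22), a wall-associated kinase (AK100387, log2 0.85 ± 0.14), an S-receptor-like kinase (AK109689, log2 0.87 ± 0.081) and nicotianamine synthase 3 (AK070656, log2 0.85 ± 0.13). Of 416 called probes, 204 were higher and 212 lower (49.0% higher), 24 of them by at least 1. In the cell wall list 5 of 63 were lower and 2 higher (9 and 2 adjusted over the list alone) (median log2 -0.086, adjusted p = 0.0011, 0.408 with an estimated correlation and 0.0184 by fry), including a pectinesterase (AK071465, log2 -0.76 ± 0.057). Tissue markers moved with it, as 6 of 35 were higher and 0 lower (12 and 1 adjusted over the list alone) in photosynthesis (median log2 0.16, adjusted p = 1.82e-05, 0.416 with an estimated correlation and 0.0777 by fry). Its member chlorophyll-binding RCABP69 (AK058293) was at log2 0.60 ± 0.071. Root markers were lower as a list. Here 1 of 9 were lower and 0 higher (3 and 0 adjusted over the list alone) (median log2 -0.050, adjusted p = 0.0167, 0.439 with an estimated correlation and 0.0482 by fry). Its member RCc3 (AK062381) was at log2 -0.79 ± 0.085, adjusted p = 0.0166. In phosphate scavenging 1 of 25 were lower and 0 higher (2 and 0 adjusted over the list alone) (median log2 -0.088, adjusted p = 0.0438, 0.416 with an estimated correlation and 0.0462 by fry), and cytosolic ribosomal proteins had 6 of 31 positive and none called (0 by limma; median log2 -0.078, adjusted p = 0.00768, 0.651 with an estimated correlation and 0.414 by fry). Without the dye term 68 probes passed, without AK071447 and AK070360, and median centring alone gave 10 (90% higher). Leaving out replicate 1 or 2 of this group gave 11 (72.7% higher) and 47 (78.7% higher).

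The mean of the 4 groups asked which transcripts differed between genotypes on average, so a call need not hold in each group. The LTR-retrotransposon-like AK106705 (log2 2.00 ± 0.042, adjusted p = 1.31e-05, n = 8 arrays), malic enzyme AK070360 (log2 1.51 ± 0.11, adjusted p = 0.00174) and reverse transcriptase-like AK064186 (adjusted p = 2.95e-05, at least 2.13-fold and 2.37-fold in roots without and with phosphorus) were higher. The S-like ribonuclease AK061438 (adjusted p = 0.00998, saturated in 1 channel of each genotype in shoots without phosphorus), SUVH2-like AK067172 (log2 -1.01 ± 0.032, adjusted p = 8.14e-05) and the hydrogenase-like AK060417 (log2 -0.99 ± 0.057) were lower. In total 1026 probes passed, 662 higher and 364 lower (64.5% higher), 17 of them by at least 1. Phosphate scavenging genes had 0 of 25 positive. Here 3 of 25 were lower and 0 higher (9 and 0 adjusted over the list alone) (median log2 -0.076, adjusted p = 4.84e-07, 0.357 with an estimated correlation and 0.0088 by fry). Its member PAP22 (AK073222) was at log2 -0.27 ± 0.051. High-affinity phosphate transporter 2 (AK108907, log2 -0.28 ± 0.041) was lower, and in the list of transporters and SPX proteins 3 of 11 were lower and 0 higher (4 and 0 adjusted over the list alone) (median log2 -0.072, adjusted p = 0.00311, 0.11 with an estimated correlation and 0.00723 by fry). In the cell wall list 6 of 63 were lower and 2 higher (13 and 2 adjusted over the list alone) (median log2 -0.040, adjusted p = 0.000275, 0.367 with an estimated correlation and 0.0171 by fry), and of the root markers 2 of 9 were lower and 0 higher (2 and 0 adjusted over the list alone) (median log2 -0.055, adjusted p = 0.0426, 0.465 with an estimated correlation and 0.0777 by fry). Defence proteins were not called by camera but were by fry (adjusted p = 0.199 and 0.0159). Here 12 of 71 were higher and 3 lower (15 and 4 adjusted over the list alone), including OsChib3a (AK100973, log2 0.83 ± 0.050) and PBZ1 (AK099157, log2 0.72 ± 0.088). Phenylpropanoids were also called by fry alone (adjusted p = 0.0478, camera 0.52). Lipoxygenase CM-LOX2 (AK066825, log2 0.76 ± 0.10) and allene oxide synthase (AK066138, log2 0.45 ± 0.089), enzymes of oxylipin and jasmonate synthesis, were higher. With no dye term 351 probes passed (74.9% higher) and AK061438 and PAP22 did not, and median centring alone gave 147 (76.2% higher). Leaving out a shoot array with phosphorus (replicate 1 or 2) gave 384 and 357, a root array without phosphorus 594 and 560, and a root array with phosphorus 393 and 555.

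The knockdown effect in shoots differed between phosphorus levels for a pair of nucleases, aspartic proteases and a tryptophan synthase. A positive difference means a higher ratio of knockdown to wild type without phosphorus. Phosphoribosyl pyrophosphate synthase (AK109735, log2 1.18 ± 0.057, adjusted p = 0.0103, n = 2 arrays per level) and tryptophan synthase alpha (AK066734, log2 0.89 ± 0.068, adjusted p = 0.0237) had positive differences. An isoflavone reductase-like protein (AK109339, log2 -1.43 ± 0.14, adjusted p = 0.0406), branched-chain amino acid transaminase (AK105963, log2 -1.34 ± 0.10, adjusted p = 0.0237), nuclease I (AK059608, log2 -0.91 ± 0.10), a bnuc2-like nuclease (AK106059, log2 -0.84 ± 0.089) and aspartic proteases (AK072645 and AK072283, log2 -0.78 and -0.77) had negative ones. In all 55 probes passed, 11 positive and 44 negative. By camera alone, cytosolic ribosomal proteins (26 of 31 positive, median log2 0.37, adjusted p = 2.07e-10, 0.457 with an estimated correlation and 0.0853 by fry) and histones (median log2 0.088, adjusted p = 0.0227, 0.497 with an estimated correlation and 0.133 by fry) had positive differences. Phosphate sensing and transport (0 of 7 positive, median log2 -0.16, adjusted p = 0.0395, 0.439 with an estimated correlation and 0.101 by fry), phosphate scavenging (median log2 -0.11, adjusted p = 0.0131, 0.408 with an estimated correlation and 0.0159 by fry) and phenylpropanoids (median log2 -0.077, adjusted p = 0.00466, 0.416 with an estimated correlation and 0.0477 by fry) had negative ones. No member of these lists was called (0 by limma). Fry alone called defence proteins (adjusted p = 0.0462, camera 0.133). The list of transporters and SPX proteins gave 0 of 11 positive (median log2 -0.20, adjusted p = 0.000723, 0.103 with an estimated correlation and 0.00723 by fry). Without the dye term 3 probes passed, with processed signals or median centring 0 passed by limma (3850 and 2495 at an unadjusted p under 0.05), and with shoot arrays alone 229 did (41.0% positive, against 20%, 52 shared). Dropping replicate 1 without phosphorus, or replicate 1 or 2 with phosphorus, gave 0 (3062, 2164 and 2447 unadjusted), and leaving out replicate 2 without phosphorus gave 66 (39.4% positive), 13 of them among the 55.

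In roots, the knockdown effect differed between phosphorus levels for 10 probes, 6 positive and 4 negative. Arginine decarboxylase (AK058573, log2 1.90 ± 0.17, adjusted p = 0.0485, n = 2 arrays per level) and an arabinofuranosidase/xylosidase (AK101782, log2 0.87 ± 0.078) had positive differences. Alanine aminotransferase (AK107237, log2 -1.40 ± 0.10, adjusted p = 0.0485), cytosolic fructose-1,6-bisphosphatase (AK070516, log2 -0.77 ± 0.061) and glycerophosphodiester phosphodiesterase (AK071836, log2 -0.68 ± 0.062) had negative ones. Photosynthesis genes had a negative difference as a list (median log2 -0.18, adjusted p = 1.14e-05, 0.416 with an estimated correlation and 0.117 by fry), while root markers (median log2 0.20, adjusted p = 0.0108, 0.416 with an estimated correlation and 0.0871 by fry), cell wall genes (median log2 0.060, adjusted p = 0.0131, 0.408 with an estimated correlation and 0.0458 by fry) and cytosolic ribosomal proteins (median log2 0.15, adjusted p = 0.000868, 0.63 with an estimated correlation and 0.382 by fry) had positive ones. No member of these lists was called (0 by limma), and fry alone called phosphate scavenging (adjusted p = 0.0478, camera 0.0859). All the gene calls ended without the dye term, with processed signals and with root arrays alone (0 probes each by limma, with 874, 1721 and 1871 at an unadjusted p under 0.05). Leaving out replicate 1 or 2 without phosphorus gave 0 (1799 unadjusted) and 1, which was not among the 10. Leaving out replicate 1 or 2 with phosphorus gave 2, of which 1 was among them, and 0 (1235 unadjusted).

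Between tissues, the knockdown effect was lower in roots than in shoots for a germin-like protein, a laccase and a flavanone 3-hydroxylase, and higher in roots for a multidrug resistance homolog and a syntaxin. Germin-like protein 6 (AK109057, log2 -1.90 ± 0.14, adjusted p = 0.0059, n = 4 arrays per tissue), copalyl diphosphate synthase-like AK072928 (log2 -1.53 ± 0.18, adjusted p = 0.0218), the laccase AK103094 (log2 -1.42 ± 0.072, adjusted p = 0.00163), tryptophan decarboxylase AK069031 (log2 -1.27 ± 0.090, adjusted p = 0.00512) and flavanone 3-hydroxylase AK071218 (log2 -1.17 ± 0.052, adjusted p = 0.00149) had negative differences. Multidrug resistance protein homolog AK106698 (log2 0.99 ± 0.090, adjusted p = 0.0105), hydrogenase-like AK060417 (log2 0.97 ± 0.11), syntaxin AK065950 (log2 0.76 ± 0.10) and cycloartenol synthase AK066327 (log2 0.62 ± 0.048) had positive ones. Altogether 241 probes passed, 70 positive and 171 negative (29.0% positive). Photosynthesis genes had a positive difference as a list (median log2 0.15, adjusted p = 0.000146, 0.416 with an estimated correlation and 0.132 by fry), and defence proteins (2 of 71 called, median log2 -0.038, adjusted p = 0.0235, 0.416 with an estimated correlation and 0.0286 by fry) and cytosolic ribosomal proteins (median log2 -0.077, adjusted p = 0.0167, 0.702 with an estimated correlation and 0.451 by fry) had negative ones. Among defence members, PR-1a (AK071103) had a difference of log2 -0.97 ± 0.14, adjusted p = 0.0374 and a chitinase (AK070067) of log2 -0.62 ± 0.066. With no dye term 66 probes passed, with processed signals 49, with median centring 0 (1899 at an unadjusted p under 0.05, limma), and with tissue means alone 60 (43.3% positive). Dropping replicate 1 or 2 of shoots with phosphorus gave 31 and 64 (15.6% positive), of roots with phosphorus 74 (16.2%) and 156, and replicate 2 of roots without phosphorus 78.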

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

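The tests of shoot material, of mobile elements as a class, of a fixed difference between the lines and of probes that fell or rose in shoots, the bootstrap intervals, the limit to splits that balance the dyes, and the fit of tissue means, were chosen after the results were seen. The values that follow were picked out because the effect of the knockdown differed between groups by a test of the difference itself, limma for probes and camera with a preset correlation for lists.

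Between phosphorus levels in shoots, 55 probes differed. Positive differences were log2 1.18 for phosphoribosyl pyrophosphate synthase (AK109735), 0.89 for tryptophan synthase alpha (AK066734), 0.73 for a cell wall invertase (AK072276) and 0.66 for WRKY51 (AK108555). Negative ones were -1.43 for an isoflavone reductase-like protein (AK109339), -1.34 for branched-chain transaminase (AK105963), -1.08 for CYP71D4 (AK111441), -0.98 for a glycine-rich protein (AK064310) and -0.92 for blt101 (AK070872). List medians of the difference were -0.16 for phosphate sensing and transport, -0.11 for phosphate scavenging, -0.077 for phenylpropanoids, 0.37 for cytosolic ribosomal proteins and 0.088 for histones. In the same order, these camera calls had adjusted p = 0.439, 0.408, 0.416, 0.457 and 0.497 with an estimated correlation and 0.101, 0.0159, 0.0477, 0.0853 and 0.133 by fry, with no member called (0 by limma).

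Between phosphorus levels in roots, 10 probes differed, with log2 1.90 for arginine decarboxylase (AK058573), 0.87 for an arabinofuranosidase (AK101782), -1.40 for alanine aminotransferase (AK107237), -0.77 for fructose-1,6-bisphosphatase (AK070516) and -0.68 for glycerophosphodiester phosphodiesterase (AK071836). List medians were -0.18 for photosynthesis, 0.15 for cytosolic ribosomal proteins, 0.060 for cell wall genes and 0.20 for root markers. These camera calls had, in that order, adjusted p = 0.416, 0.63, 0.408 and 0.416 with an estimated correlation and 0.117, 0.382, 0.0458 and 0.0871 by fry, again with 0 members called.

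Between root and shoot, 241 probes differed. Positive differences were log2 0.99 for a multidrug resistance homolog (AK106698), 0.97 for a hydrogenase-like protein (AK060417), 0.76 for a syntaxin (AK065950), 0.64 for an S-receptor-like kinase (AK109689) and 0.62 for cycloartenol synthase (AK066327). Negative ones were -1.90 for germin-like protein 6 (AK109057), -1.87 and -1.66 for N-1 type cytochromes P450 (AK070167 and AK065971), -1.53 for a copalyl diphosphate synthase-like gene (AK072928) and -1.42 for a laccase (AK103094). List medians were 0.15 for photosynthesis, -0.038 for defence proteins and -0.077 for cytosolic ribosomal proteins. Here the camera calls had adjusted p = 0.416, 0.416 and 0.702 with an estimated correlation and 0.132, 0.0286 and 0.451 by fry, with 0, 2 and 0 members called. With tissue means only, 60 probes differed. Of 34 splits of the 8 arrays into 4 and 4, 18 balance the dye orientation as the real one does, and 1 of these, the real one, gave as many (highest other 0 by limma, with 135 to 2233 probes at an unadjusted p under 0.05). These are too few for a share under 0.05, and the highest other of all 34 was 3.

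For the mean of the 4 groups, 1026 probes were called. Of the sets of array sign turns, 8 keep both dye orientations in every group, and 1 of these, the real one, gave as many, with 337 the highest other. These 8 are too few for a share under 0.05. Each turns both arrays of a group or neither, so the other sets keep the genotype effects, with signs changed between groups. The 337 is therefore no measure of the count without a genotype effect. The 100 sets drawn from the 120 of all 128 that could be fitted also gave at most 337 beside the real one, but most of them tie the mean to the dye.

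By camera at the preset correlation, photosynthesis genes were lower as a list in roots without phosphorus in both genotypes, which shared arrays and are not independent. Fry called both too, but neither held with an estimated correlation, and only a minority of members was called. The list's median change kept at least 0.903 of its size with median alignment or no background correction. This argues against the choice of Aquantile over median alignment as the cause. A fault shared by both alignments was not tested, and the setting without background correction kept Aquantile. Shoot material in the root samples grown with phosphorus stays open. Its test took probes abundant in shoots and scarce in roots without phosphorus, chosen on 1 replicate and measured on the other. Outside photosynthesis, 80% to 85.3% were higher with phosphorus, against 45.0% to 52.3% of probes of like root level not abundant in shoots. The share of the shoot level they needed was 0.692 and 0.593 (wild type) and 0.665 and 0.388 (knockdown) of that of 6 photosynthesis probes, around the bound of 0.5, while the test as first planned, with probes chosen on the arrays then measured, gave 0.684 and 0.557, which that choice favours. A greening of roots with phosphorus, which would bring plastid transcripts too, stays open and was not tested.

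By camera at the preset correlation, phosphate starvation genes were lower as lists in the knockdown shoots without phosphorus. Of phosphate scavenging 5 of 25 members were called lower, and of phosphate sensing and transport 0 of 7. With an estimated correlation camera gave adjusted p = 0.408 and 0.445, and fry gave 0.0106 and 0.117. In 364 probes chosen from the root arrays for rising in wild type roots, the ratio of knockdown to wild type had medians of -0.23 and -0.23 without phosphorus and 0.0040 and 0.025 with it, so shared wild type channels, which predicted a difference within 0.05 of 0, are argued against by -0.24 (the higher replicate). Signal bias is argued against as well, since 0 of 10000 random sets matched on signal were as low, the lowest being -0.039. The difference of the knockdown effect between phosphorus levels is the same quantity as the knockdown response minus the wild type response. A negative value in rising genes is therefore a smaller rise in knockdown shoots, not a separate cause. Whether falling genes also fell less stays open. The 240 probes that fell in wild type roots had medians of -0.0091 and -0.00022. Those of them that also fell in wild type shoots of the other replicate (142 and 147 probes) had 0.026 and 0.045. Their 95% bootstrap intervals over probes were -0.031 to 0.078 and -0.0066 to 0.083, around the bound of 0.05. The 138 and 427 that fell by at least 1 in wild type shoots of the other replicate had 0.34 (0.24 to 0.38) and 0.065 (0.038 to 0.095). Both of these intervals lie above 0, but the second reaches below the bound of 0.05. The 335 and 463 probes that rose by at least 1 in wild type shoots of the other replicate had -0.34 (-0.38 to -0.29) and -0.28 (-0.33 to -0.25). Of these, 18.5% and 12.7% were positive. These probes rose in the wild type shoots measured (medians 1.18 and 0.97) and thus rose less in knockdown shoots. What stays open is whether the weaker response extends to the falling genes. Cytosolic ribosomal proteins, which fell in wild type shoots (median -0.59), had a positive difference (0.37, 26 of 31 positive, adjusted p = 2.07e-10 by camera, 0.457 with an estimated correlation and 0.0853 by fry). Both values use the same wild type shoot channels, which favours opposite signs, so this pair cannot decide the question. For wild type shoots 1597 probes passed, against 481 for knockdown shoots, but such counts do not test the difference.

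Of 17 probes with a mean change of at least 1 over the 4 groups, 16 kept their direction on all 8 arrays. Release of mobile elements as a class stays open: the median of 70 such probes was -0.0069 (mean 0.0624), 5 were higher and 0 lower, camera did not call the list (adjusted p = 0.809) and fry did (adjusted p = 0.00461). The list was chosen after these ratios were seen, so the fry call is no independent evidence. A ratio constant over groups is argued against for the 10 probes with a called difference. A fixed difference between the lines stays open for them, as ratio shrinkage at low signal or saturation was not tested. Among the other 7, it may account for AK106705, AK064186, AK067172, AK070360, AK062961 and AK071155, with no called difference. The last, AK061438, had no called difference either, but its arrays ranged from log2 -3.58 to -0.089 (SE of the mean change 0.14). It was also saturated in shoots without phosphorus, so the missing call does not show a constant change. Beside release of mobile elements as a class, no biological explanation was tested for these 7 probes.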

How the results depend on the processing

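The fit of tissue means was chosen after the results were seen, and the 2 added lists after the descriptions were read. Counts are given in the order shoot without and with phosphorus, root without and with phosphorus, mean, shoot difference, root difference and difference between root and shoot. Processed signals gave 250, 192, 20, 84, 575, 0, 0 and 49, and the deposited ratios 298, 194, 22, 83, 590, 0, 0 and 49. Median centring gave 19, 61, 3, 10, 147, 0, 0 and 0, and no dye term 136, 138, 12, 68, 351, 3, 0 and 66. The counts of 0 are limma's, with 1023 to 3866 probes at an unadjusted p under 0.05 except 874 for the root difference without the dye term. A minimum change of 1 gave 56, 59, 14, 24, 17, 8, 5 and 33, and 477, 604, 189 and 718 for the phosphorus responses of wild type shoot and root and knockdown shoot and root, by its stricter threshold. Arrays of the same tissue gave 229 for the shoot difference, 0 for the root difference (1871 unadjusted), and 4 and 30 for roots without and with phosphorus. No background correction gave 1 for the root difference, and tissue means gave 60 between root and shoot. The phosphorus response of knockdown shoots had 170 with processed signals, 729 without the dye term and 726 with knockdown channels alone. Apart from the minimum change, the cause was not tested.

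Leaving out 1 array gave 165 to 170 (shoot without phosphorus), 21 to 57 (shoot with), 10 to 22 (root without), 11 to 47 (root with), 357 to 883 (mean), 0 to 66 (shoot difference), 0 to 2 (root difference) and 31 to 211 (between tissues), with fewer arrays per group as part of the cause. The phosphorus responses ranged from 372 to 1275 (wild type shoot), 689 to 1391 (wild type root), 77 to 387 (knockdown shoot) and 947 to 2123 (knockdown root). In all, 91 counts moved by more than 1.5 times and 68 did not.

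Of 57 list calls, 0 held with an estimated correlation (camera, smallest adjusted p = 0.357), 35 by fry, 46 with processed signals and 52 without the dye term. For 511 named results, 6604 alternative values gave 0 reversals, 4628 kept their call and 1976 lost it. Loess mattered most for named ratios, as 33 of 267 kept their call with median centring, against 502 of 511 without background correction. A block for slide or scan day was not run, nor were alternatives for OsPI1, for which no probe could be identified by description. Signal over background limited few probes, as 21058 of 21495 passed the filter.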

Other observations

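The lists in this part, and their tests, were chosen after the ratios of knockdown to wild type were seen. Genes of diterpenoid synthesis, which in rice leads to phytoalexins against microbes, were higher in knockdown shoots. With phosphorus 9 of 22 were higher and 0 lower (14 and 0 adjusted over the list alone), with 20 positive (median log2 0.40, adjusted p = 4.19e-15, 0.074 with an estimated correlation and 0.00283 by fry), including the PM-II cytochrome P450 AK105913 (log2 2.34 ± 0.34) and deoxyxylulose phosphate synthase AK100909 (log2 1.71 ± 0.12). Without phosphorus 5 of 22 were higher and 0 lower (9 and 0 adjusted over the list alone) (median log2 0.12, adjusted p = 2.26e-05, 0.074 with an estimated correlation and 0.011 by fry). In roots none of the 22 was called (0 by limma; adjusted p = 0.916 and 0.879 for the list without and with phosphorus). The difference between root and shoot was negative (median log2 -0.26, adjusted p = 1.59e-11, 0.074 with an estimated correlation and 0.00283 by fry), as was that between phosphorus levels in shoots (median log2 -0.24, adjusted p = 6.94e-05, 0.074 with an estimated correlation and 0.0131 by fry). In knockdown shoots 3 of 21 fell and 0 rose (5 and 0 adjusted over the list alone) without phosphorus (median log2 -0.22, adjusted p = 0.000378, 0.163 with an estimated correlation and 0.0193 by fry), while wild type shoots gave adjusted p = 0.952 with 0 called.

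Genes of the tryptophan branch, which supplies tryptamine and other indole compounds, were higher in the same shoots. Without phosphorus 5 of 10 were higher and 0 lower (7 and 0 adjusted over the list alone), with all 10 positive (median log2 0.40, adjusted p = 3.08e-08, 0.074 with an estimated correlation and 0.00283 by fry), led by tryptophan decarboxylase AK069031 (log2 1.95 ± 0.090). With phosphorus 4 of 10 were higher and 0 lower (4 and 0 adjusted over the list alone) (median log2 0.18, adjusted p = 0.00104, 0.119 with an estimated correlation and 0.014 by fry). The difference between phosphorus levels was positive (median log2 0.35, adjusted p = 1.54e-05, 0.074 with an estimated correlation and 0.0112 by fry), opposite in sign to that of the diterpenoid list. Between root and shoot it was negative (median log2 -0.28, adjusted p = 6.75e-07, 0.074 with an estimated correlation and 0.00461 by fry). In wild type shoots 2 of 10 fell and 0 rose (2 and 0 adjusted over the list alone) without phosphorus (median log2 -0.27, adjusted p = 0.0116, 0.171 with an estimated correlation and 0.0175 by fry). Transposable elements were not called by camera, which compares a list with other genes, in any of 12 comparisons (for the mean of the 4 groups median log2 -0.0069, adjusted p = 0.809, 0.836 with an estimated correlation and 0.00461 by fry). By fry, which does not, the list was called in shoots without and with phosphorus (adjusted p = 0.0187 and 0.0187), in roots (0.0259 and 0.0251) and for the mean (0.00461).

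A few probes described as unknown changed more than any named gene of the same comparison, and were picked after their values were seen. AK108619, saturated in the knockdown channel of 1 array, and AK102606 were higher in the knockdown over the 4 groups, AK102606 by log2 2.77, with the same direction on all 8 arrays. In wild type roots AK063904, saturated without phosphorus in 1 of 2 replicates, rose.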
